A study of Mus musculus with 22 samples.

How the data were processed

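Total RNA from the fourth left mammary gland of individual female C57BL/6 mice was profiled by the authors with a NanoString nCounter mouse miRNA panel, in which each miRNA is counted directly through a fluorescent barcode. The labels describe 4 diets given for 3 weeks, starting at 4 to 5 weeks of age, with 6 mice randomized to each. The diets were the basal AIN-93G diet, 10% flaxseed, 3.67% flaxseed oil and 0.15% secoisolariciresinol diglucoside (SDG, the main lignan of flaxseed). RNA of each gland ran in its own lane, and lanes are named by diet and replicate number. The 2 lanes that the authors had excluded (basal 5 and oil 5, for too few probes above background) were not analysed here, which left 5 basal, 6 flaxseed, 5 oil and 6 SDG lanes.

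Per the file headers and the labels, the deposited lane files hold raw counts per probe, with no scaling by the authors; all values were whole numbers. A separate deposited table of log2 values, scaled and background-subtracted by the authors by a rule the labels do not state, holds 238 miRNAs. The counts were the basis of all comparisons, and the log2 table served as an alternative. Each lane had 599 endogenous probes (566 mouse and 33 viral), 6 positive, 8 negative, 6 ligation, 4 housekeeping mRNA and 3 spike-in probes; only endogenous probes entered library sizes and tests. Probe names were shortened by removing the species prefix, and probes that detect several miRNAs keep all names joined by a plus sign.

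A probe was tested if its count exceeded the mean plus 2 SD of the 8 negative controls of the same lane in at least 5 of 22 lanes. This retained 254 probes, 1 of them viral. The threshold ranged from 17.5 to 66.8 counts between lanes. All 22 lanes entered a single edgeR quasi-likelihood fit (edgeR 4.0.16 in R 4.3.3) with trimmed-mean (TMM) scaling and diet as the factor. The 6 pairwise comparisons of diets were read from this fit, with an F-test for any difference of the 3 flaxseed-derived diets from basal. P values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Log2 fold changes are given with approximate standard errors (SE), and levels as log2 CPM (counts scaled to a common library size, with 1 count added) with SD. Each SE was derived as the size of the log2 fold change over the square root of its quasi-likelihood F statistic. The 95% intervals of log2 fold changes were built from these SE. Counting intervals of the miR-720 share are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

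Before the data were examined, 22 miRNA lists were fixed: cell-type markers (luminal and epithelial, basal and keratinocyte, adipocyte, lymphocyte and myeloid, muscle, erythrocyte, endothelial, fibroblast, neuronal, liver and pancreas), families and genomic clusters (let-7, miR-17/92 with its paralogs, miR-29, miR-30, miR-34, Dlk1-Dio3, Sfmbt2, miR-290 with miR-302, and an X-linked testis cluster), and estrogen receptor, breast oncogenic and breast tumour suppressor associated miRNAs. The 20 lists with at least 3 tested probes were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists within a comparison. The miR-290 with miR-302 list and the X-linked list had 1 tested probe each and were not tested. Calls were repeated with camera's estimated correlation between members and with fry. Lists overlap: of the 9 members of the miR-17/92 list 4 stand in another list, of the 14 lymphocyte and myeloid members 6, of the 5 muscle members 1, and of the 22 Dlk1-Dio3 members 0.

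Named miRNAs followed a rule fixed in advance: those past the threshold, filled up to 10 by smallest unadjusted p where fewer passed, the 2 leading members of each list in the comparisons with basal, and 20 fixed miRNAs. The 10 leading miRNAs of each comparison, and the list leaders with unadjusted p under 0.1 in the comparisons with basal, were carried through all alternatives. That limit of 0.1 was chosen after values had been seen, and the other miRNAs of the rule were not carried through. List members named beyond these were chosen after their values were seen.

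Alternatives fixed in advance were DESeq2 (1.42.0), limma-voom, DESeq2 size factors, scaling by the 100 most abundant probes, by housekeeping mRNAs, by positive controls or by total count, no filter, a stricter filter (220 probes), negative control subtraction, fits of only the diets compared, replicate number as a block, limma on the deposited log2 table, and leaving out each lane in turn. Added after the data had been seen were fits without 3 lanes in which miR-720 exceeded 40% of the counts (with the filter recomputed, or with the 254 probes kept), mouse probes only, total count without miR-720, housekeeping scaling without flaxseed 3, and, for the lists, the level of lymphocyte miRNAs (miR-150 and miR-142-3p) as a covariate, with camera's estimated correlation repeated without the 3 lanes and with the covariate. Quality measures were compared with two-sided exact permutation tests over 462, 252 or 924 splits of the lanes. For each count, 100 splits of the same lanes were drawn with a fixed seed.

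The workflow was tested on data simulated at the depth and dispersion of this series, with 48 of 254 miRNAs changed in 5 oil against 5 basal lanes in each of 20 simulations. It called 54.1% of 2-fold, 92.2% of 4-fold and 98.4% of 8-fold changes, and 0.971% of the unchanged miRNAs. A shift of -0.5 placed on a list of 22 was called in 20 of 20 simulations, and 0 of 400 unshifted lists were called. Probes were simulated independently, so that the list test was not tested with correlated members.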

Results

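The series measured miRNAs in 22 mammary glands of young female mice fed a basal diet (n = 5), 10% flaxseed (n = 6), 3.67% flaxseed oil (n = 5) or 0.15% SDG (n = 6). The comparisons ask how whole flaxseed and its oil and lignan components relate to miRNA levels in the gland. Endogenous counts per lane ranged from 260551 (SDG 1) to 762146 (basal 6). Their means were 486500 ± 175400 (SD) in basal, 484100 ± 142500 in flaxseed, 558200 ± 128400 in oil and 392000 ± 150800 in SDG lanes. Between 29.0% and 47.9% of a lane's 599 endogenous probes lay above its background threshold. None of 24 two-sided exact permutation tests of counts, background and controls between diets passed adjustment. Complete separation of a pair of diets in a single measure could not have passed over 24 tests, so technical differences are not excluded. The smallest p was for the positive controls, whose geometric mean was 1356 ± 92.4 (SD) in SDG and 1146 ± 86.4 in basal lanes (exact p = 0.00866, adjusted p = 0.208). It was also higher in SDG than in flaxseed lanes, at 1177 ± 129 in the latter (exact p = 0.0195, adjusted p = 0.234). In oil lanes it was 1294 ± 110.5 (SD, exact p = 0.0556 and adjusted p = 0.413 against basal lanes).

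Probes differ in efficiency, so that levels are not ranked between miRNAs. Among the probes with the highest counts besides miR-720 were let-7b, at 15.49 ± 0.51 log2 CPM (SD, n = 22), let-7g, at 15.40 ± 0.42, and endothelial miR-126-3p, at 15.38 ± 0.35. Of the stromal and smooth muscle miRNAs, miR-199a-3p stood at 14.91 ± 0.54, miR-143 at 14.46 ± 0.76 and miR-145 at 14.34 ± 0.66. In the 5 basal lanes miR-205, a marker of basal and myoepithelial cells, stood at 12.13 ± 1.05 and luminal miR-200c at 9.85 ± 0.78. In 3 lanes miR-720, a fragment of a transfer RNA, took a large share of the count. The share was 65.4% in basal 1 (95% exact binomial interval 65.3% to 65.6%), 53.7% in flaxseed 3 (53.6% to 53.8%) and 47.4% in SDG 5 (47.2% to 47.5%). In the other 19 lanes it lay between 2.37% and 8.61%, and no oil lane was among the 3.

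**Figure D1:**
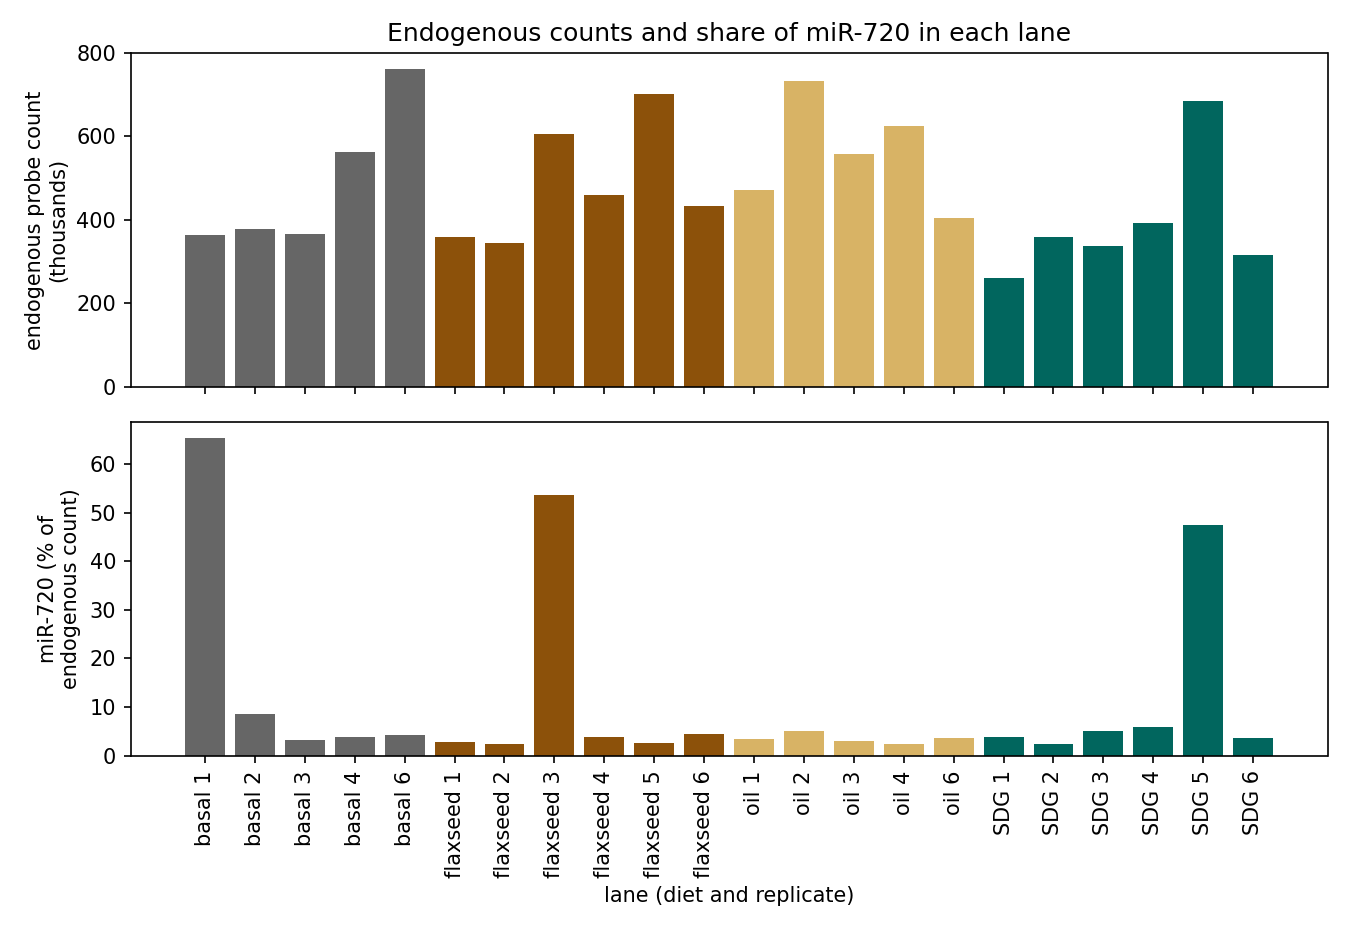
Total endogenous probe count (top) and share of miR-720 in percent (bottom) for each of the 22 lanes, colored by diet. miR-720 took 65.4%, 53.7% and 47.4% of the counts in basal 1, flaxseed 3 and SDG 5, and at most 8.61% in any other lane.

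In edgeR, 0 of 254 miRNAs passed the adjusted threshold in each of the 6 comparisons of diets and in the test for any diet, where 36 had an unadjusted p under 0.05 (smallest adjusted p = 0.213). limma-voom also called 0 in each of these tests. DESeq2, run on the 6 comparisons, called 6 miRNAs between oil and basal, 30 between flaxseed and oil and 0 in the others. The median SE of a log2 fold change was 0.29 to 0.32 and the median half-width of its 95% interval 0.61 to 0.67, so that smaller changes were not detectable for most miRNAs. This half-width holds for a single test, and adjustment over 254 miRNAs requires larger changes. In the simulations, with 48 of 254 miRNAs changed and probes drawn independently, 54.1% of 2-fold changes in oil were called. Fewer changed miRNAs or correlated probes were not simulated, so this share need not hold for the measured lanes. The miRNA lists named under each comparison were called by camera with its preset correlation. With an estimated correlation 0 lists were called in any comparison of all lanes. Median, mean and test differed in sign in 19 of 120 list tests, of which 0 were called.

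Oil against basal asks about the oil fraction. It showed lower muscle miRNAs, lower miRNAs of the imprinted Dlk1-Dio3 cluster and higher miR-17/92 miRNAs as groups. Of the 5 muscle miRNAs 4 lay below 0, with log2 fold changes of -5.44 ± 1.76 (SE; n = 5 and 5) for miR-1, -4.89 ± 1.41 for miR-133a and -2.83 ± 0.76 for miR-133b, which act in striated muscle differentiation. The basal level of miR-1 rested on basal 3 and basal 4, with 33870 and 96794 counts against 123 to 843 in the other 3 basal lanes, and its mean log2 CPM was 12.85 ± 3.97 (SD) in basal and 9.43 ± 1.76 in oil lanes. In basal 2 and basal 6 miR-133a, at 5.33 and 6.33 log2 CPM, lay within the range of the oil lanes. Its counts of 35, 20 and 24 in oil 2, oil 3 and oil 4 lay below the lane's background threshold, so the size of its fall is uncertain. miR-133b had a mean count of 17.8 in oil lanes, below the mean background threshold of 40.9. The Dlk1-Dio3 list, a large cluster expressed from the maternal allele, had 21 of 22 members below 0 and a median of -0.42. Under housekeeping, positive control and total count scaling its median was -0.17, -0.19 and -0.19. Against all miRNAs it stood at -0.48, -0.48 and -0.47 there. The list was led by miR-410 at -0.90 ± 0.33 and miR-411 at -0.75 ± 0.28, and the median of its members' mean counts was 117. The basal level of miR-410 was raised by basal 1, at 8.42 log2 CPM against 7.21 to 7.55 in the other basal lanes. Its oil level was lowest in oil 1, oil 3 and oil 4, at 6.34, 6.34 and 6.71, lanes in which miR-150 was high. Oil 2 and oil 6 stood at 7.26 and 7.01. All 9 members of the miR-17/92 list, paralogous clusters known for promoting proliferation, lay above 0 with a median of 0.48. Among them miR-92a stood at 1.54 ± 0.48 and miR-106b at 0.75 ± 0.24, the latter higher in each of 5 oil lanes than in any basal lane. For miR-92a oil 1, oil 3 and oil 4, at 8.21, 8.63 and 8.22 log2 CPM, lay above every basal lane, and oil 2 and oil 6, at 6.05 and 6.14, within the basal range of 5.48 to 6.75. In basal 1, basal 3 and basal 4 its counts of 16, 18 and 45 lay below the lane's background threshold, so its fold change is uncertain. With the level of miR-150 and miR-142-3p as a covariate the miR-17/92 median went to 0.29. The lymphocyte miRNAs miR-150 and miR-142-3p stood at 2.57 ± 0.78 and 2.94 ± 0.90, each above every basal lane in 3 of 5 oil lanes.

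Camera's adjusted p was 0.0348 for muscle, 2.29e-06 for Dlk1-Dio3 and 3.43e-05 for miR-17/92, and 0.545, 0.156 and 0.156 with an estimated correlation. Adjusted over the list alone, miR-1, miR-133a and miR-133b fell among 5 muscle miRNAs, and miR-92a and miR-106b rose among 9 of miR-17/92. miR-150 and miR-142-3p of the lymphocyte list also rose adjusted over the list alone, while 0 of the Dlk1-Dio3 list passed, against 0 over all 254. The lymphocyte and myeloid list as a whole had a median of 0.10 and was not called (adjusted p = 0.186). In edgeR 41 miRNAs (15 higher, 26 lower) had an unadjusted p under 0.05, with a smallest adjusted p of 0.194. DESeq2 called miR-133a, miR-133b and miR-1 lower and miR-150, miR-142-3p and miR-92a higher in oil. Further leading miRNAs were miR-501-3p at -0.77 ± 0.26, miR-338-3p at -1.06 ± 0.36 and miR-15b at 1.27 ± 0.43. The muscle call ended without basal 3, basal 4, oil 2 or oil 6, with medians of -2.64, -2.10, -2.66 and -2.89. It also ended without the 3 lanes led by miR-720 (-2.91), where miR-338-3p (-1.26) was the 1 miRNA called.

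**Figure D2:**
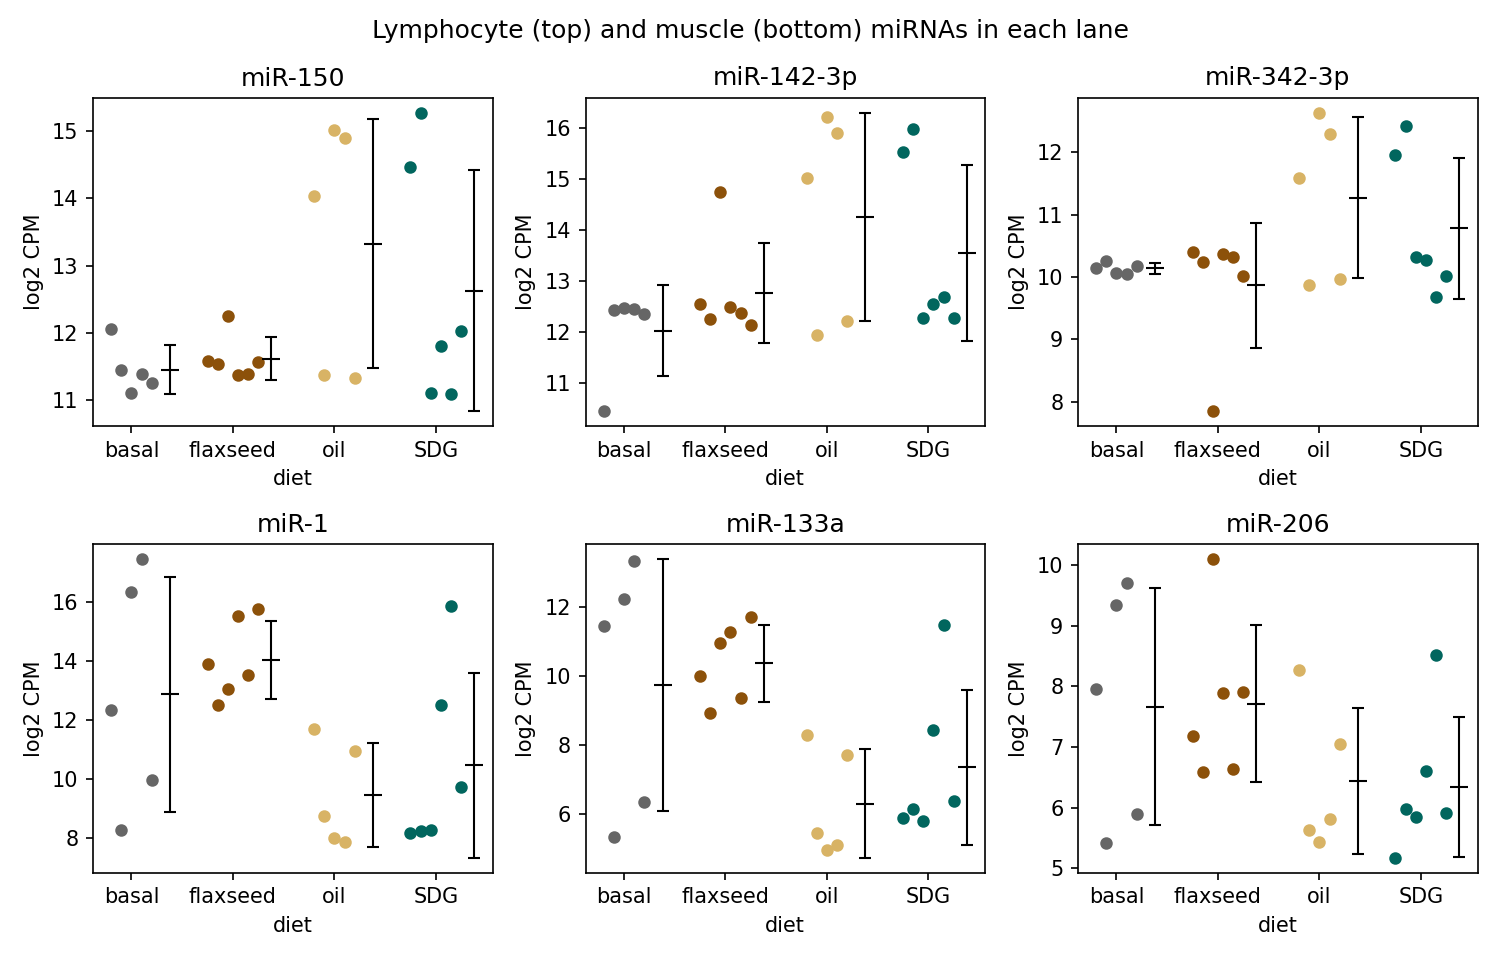
Levels of 3 lymphocyte miRNAs (top) and 3 muscle miRNAs (bottom) in log2 CPM, with each lane as a point by diet and the mean with its SD beside each group. miR-150 lay at 14.03 to 15.26 in 3 oil and 2 SDG lanes and between 11.11 and 12.25 in the basal and flaxseed lanes.

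**Figure D3:**
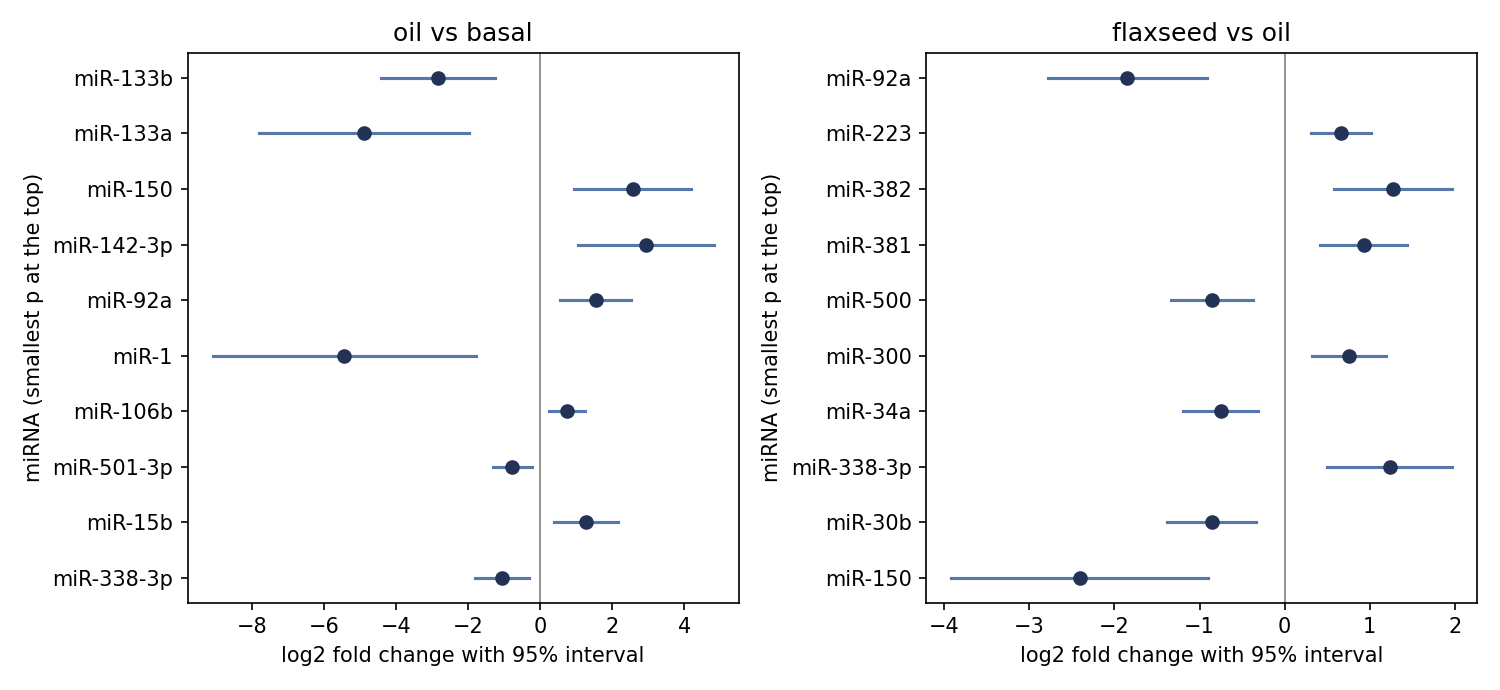
Log2 fold changes (points) with 95% intervals (lines) of the 10 miRNAs with the smallest p in oil against basal (left) and flaxseed against oil (right). None passed adjustment over 254 miRNAs in edgeR.

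SDG against basal asks about the lignan. The muscle list was lower and the miR-17/92 and lymphocyte lists higher as groups, while Dlk1-Dio3, with a median of -0.08, was not called (adjusted p = 0.825). All 5 muscle miRNAs lay below 0 with a median of -1.89, including miR-133b at -1.89 ± 0.69 (SE; n = 6 and 5), miR-133a at -2.65 ± 1.18 and miR-206 at -1.70 ± 0.82. In every SDG lane but SDG 5 miR-206, at 11 to 42 counts, lay below the lane's background threshold. miR-133a did in SDG 1, SDG 2 and SDG 3, so the sizes of these falls are uncertain. The lanes overlapped: miR-1 stood at 16.33 and 17.44 log2 CPM in basal 3 and basal 4 but at 8.24 and 9.95 in basal 2 and basal 6, and at 15.85 in SDG 5. For miR-133a basal 2 and basal 6, at 5.33 and 6.33, lay below or among the SDG lanes at 5.79 to 11.50. The muscle median was -1.14 without basal 4 and -2.68 without the 3 lanes led by miR-720. All 9 miR-17/92 members lay above 0 with a median of 0.35, which was -0.32 under positive control scaling. That scaling moved the median of all miRNAs to -0.50 and left the list 0.18 above it. Of 14 lymphocyte and myeloid miRNAs 11 lay above 0 with a median of 0.31, which was -0.24 under positive control scaling and there 0.26 above all miRNAs. miR-150 stood at 2.10 ± 0.75 and miR-142-3p at 2.26 ± 0.86, above every basal lane in 2 and 4 of 6 SDG lanes. The basal mean of miR-142-3p is lowered by basal 1, at 10.43 log2 CPM against 12.34 to 12.47 in the other 4 basal lanes, and SDG 3 and SDG 6 lay below those 4, at 12.26 and 12.27. miR-486, abundant in red blood cells and muscle, had the smallest p at -1.23 ± 0.39, followed by miR-1931 at -2.05 ± 0.69.

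Adjusted p was 0.000329 for muscle, 0.00207 for miR-17/92 and 0.0221 for the lymphocyte and myeloid list, and 0.571, 0.571 and 0.661 with an estimated correlation. Adjusted over the list alone, 0 members of these 3 lists passed, and of the 5 erythrocyte miRNAs miR-486 fell, against 0 over all 254. In edgeR 13 miRNAs (6 higher, 7 lower) had an unadjusted p under 0.05 with a smallest adjusted p of 0.785, and DESeq2 called 0. The lymphocyte call ended without basal 2, basal 3, basal 6, SDG 1 or SDG 2, with medians of 0.36, 0.28, 0.28, 0.28 and 0.17. The miR-17/92 call ended with the level of miR-150 and miR-142-3p as a covariate (0.15). It also ended without basal 1 (0.22), the basal lane led by miR-720, and miR-3471 then turned from -1.39 to 0.47.

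Flaxseed against basal, the whole seed, gave neither single miRNAs nor lists past the threshold. The leading miRNAs were miR-500 at -0.77 ± 0.23 (SE; n = 6 and 5), miR-3471 at -1.89 ± 0.62, miR-27b, which acts in adipocytes and endothelium, at 1.37 ± 0.49, and miR-2141 at 2.75 ± 0.99. Of the miR-29 family 3 of 3 members lay above 0. Of the miR-30 family 4 of 5 did, including miR-30a at 0.68 ± 0.31 and miR-30e at 1.04 ± 0.45, which turned to -0.12 without the 3 lanes led by miR-720, or -0.20 with the 254 probes kept. Muscle miRNAs had a median of -1.14 (adjusted p = 0.795). For miR-1 the fitted value was -1.16 ± 1.39 although its mean log2 CPM was 14.03 in flaxseed and 12.85 in basal lanes, where the SD was 3.97. The lymphocyte miRNA miR-150 had similar means in flaxseed (11.62 ± 0.32 log2 CPM, SD) and basal lanes (11.45 ± 0.36).

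In edgeR 22 miRNAs (15 higher, 7 lower) had an unadjusted p under 0.05, with a smallest adjusted p of 0.554, and DESeq2 called 0. The 20 lists had adjusted p values of 0.457 or more, and 0.894 or more with an estimated correlation. Without the 3 lanes led by miR-720 the liver and pancreas list of 3 was called, with a median of 0.58 (adjusted p = 0.00103, and 0.0353 with an estimated correlation). The median of its members' mean counts over all lanes was 47.1, close to the mean background threshold of 40.9. Without flaxseed 3, in which miR-720 took 53.7% of the count, miR-1224 turned from 1.55 to -0.28, and miR-27b was 0.19 and miR-2141 0.38. Without basal 1, miR-3471 was -0.05. Housekeeping scaling, which moved the median of all miRNAs to 1.39, called 67 miRNAs higher in flaxseed, and 0 once flaxseed 3 was left out.

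Flaxseed against oil compares the whole seed with its oil. It gave 60 miRNAs at an unadjusted p under 0.05 (38 higher, 22 lower in flaxseed), with a smallest adjusted p of 0.0641. The Dlk1-Dio3 cluster was higher in flaxseed as a group, with 20 of 22 members above 0 and a median of 0.63. Under housekeeping, positive control and total count scaling the median was 1.61, 0.275 and 0.354. Against all miRNAs the cluster stood at 0.457, 0.542 and 0.513 there. It was led by miR-382 at 1.28 ± 0.34 (SE; n = 6 and 5), miR-381 at 0.93 ± 0.25 and miR-300 at 0.76 ± 0.21. The miR-17/92 list was lower, with 8 of 9 members below 0 and a median of -0.49, which was 0.32 under housekeeping scaling, where all miRNAs had a median of 1.15 and the list stood at -0.83 against them. Its member miR-92a, at -1.85 ± 0.45, had a mean count of 29 in flaxseed lanes, below the mean background threshold. Myeloid miR-223 stood at 0.66 ± 0.17 and lymphocyte miR-150 at -2.41 ± 0.73. The groups overlapped for both, and the oil mean of miR-150 rested on 3 high lanes, with oil 2 and oil 6 at 11.37 and 11.33 log2 CPM near the 11.37 to 12.25 of the flaxseed lanes. The p53 target miR-34a stood at -0.75 ± 0.21, miR-500 at -0.86 ± 0.23 and miR-30b at -0.86 ± 0.25.

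Adjusted p was 2.38e-06 for the Dlk1-Dio3 list and 0.0041 for miR-17/92, and 0.454 and 0.472 with an estimated correlation. The directional test fry gave an adjusted p of 0.0337 for the former and 0.0729 for the latter. With the level of miR-150 and miR-142-3p as a covariate the miR-17/92 call ended (median -0.33, adjusted p = 0.109). Adjusted over the list alone, 9 Dlk1-Dio3 members rose and miR-92a, miR-19b and miR-106b of miR-17/92 fell, against 0 over all 254. The muscle list had a median of 1.50 and was not called (adjusted p = 0.126). Camera at its preset correlation called it under housekeeping scaling (3.92, adjusted p = 0.0127) and without oil 1 (2.20, adjusted p = 0.0228). In oil 2, oil 3 and oil 4 miR-133a of this list lay below the lane's background threshold. The list's members miR-1 (4.28 ± 1.64) and miR-133a (3.75 ± 1.32) passed adjusted over the list alone. So did miR-150, miR-223 and miR-342-3p of the lymphocyte list, miR-137, miR-30b, miR-34a and miR-125a-3p. DESeq2 called 30 miRNAs (16 higher, 14 lower). Without the 3 lanes led by miR-720 edgeR called 31 (17 higher, 14 lower) with its filter recomputed or 18 (6 higher, 12 lower) with the 254 probes kept. Leaving out 1 lane gave 7 calls without flaxseed 6 or oil 6, 2 without flaxseed 3 (miR-338-3p and miR-204), 1 without oil 2 (miR-92a) and 0 without any other.

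**Figure D4:**
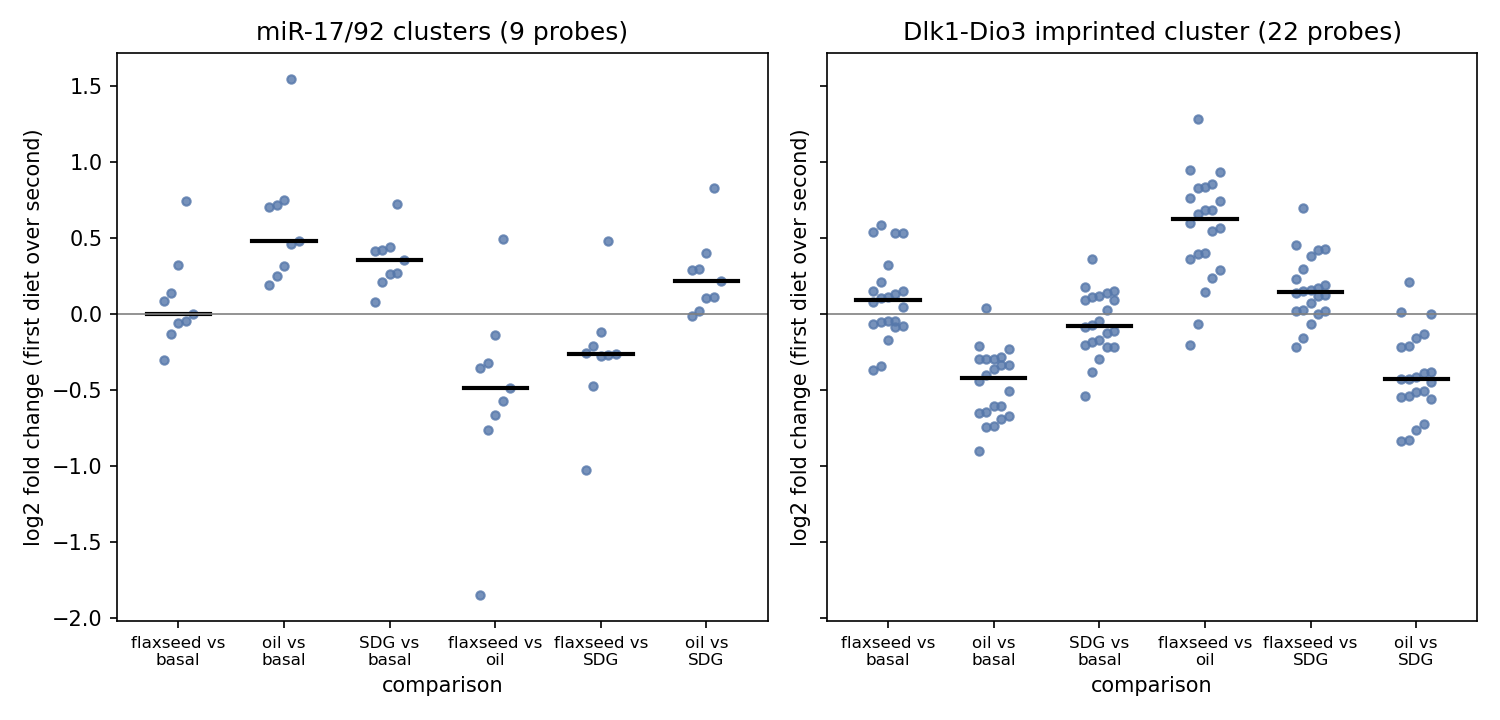
Log2 fold changes of the 9 miR-17/92 (left) and 22 Dlk1-Dio3 (right) probes in each comparison, first diet over second, with a bar at the median. Dlk1-Dio3 members lay below 0 for 21 of 22 in oil against basal and above 0 for 20 of 22 in flaxseed against oil; other scalings turned the miR-17/92 median in flaxseed against oil (0.32), flaxseed against SDG (0.33 and 0.31) and SDG against basal (-0.32), and the Dlk1-Dio3 median in oil against SDG (0.30).

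Flaxseed against SDG compares the seed with its lignan. Muscle miRNAs were higher in flaxseed as a group, with 5 of 5 members above 0 and a median of 1.10, including miR-206 at 1.47 ± 0.79 (SE; n = 6 and 6) and miR-499 at 0.49 ± 0.22. Except in SDG 5, with 148 counts, miR-206 lay below the lane's background threshold in the SDG lanes. SDG 5 went the other way, with miR-1 at 15.85 log2 CPM above every flaxseed lane (highest 15.75) and miR-133a at 11.50 above 5 of 6. The muscle median was 2.36 without SDG 5, 0.63 without flaxseed 3, 0.65 without flaxseed 6 and 1.40 without the 3 lanes led by miR-720. The miR-17/92 list was lower, with 8 of 9 members below 0 and a median of -0.27, which turned to 0.33 under housekeeping and 0.31 under positive control scaling. Relative to all miRNAs it was -0.59 and -0.17 there, with medians of all miRNAs at 0.92 and 0.48. The leading miRNAs were miR-27b at 1.50 ± 0.46, miR-150 at -1.94 ± 0.70 and let-7b at 0.81 ± 0.31. miR-378, encoded within the metabolic regulator Ppargc1b, stood at 0.74 ± 0.32, above the SDG mean in 6 of 6 flaxseed lanes, with overlap between the groups.

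Adjusted p was 0.000573 for muscle and 0.0077 for miR-17/92, both 0.641 with an estimated correlation. Adjusted over the list alone, 0 members of either passed and miR-27b of the endothelial list rose, against 0 over all 254. In edgeR 13 miRNAs (10 higher, 3 lower) had an unadjusted p under 0.05, with a smallest adjusted p of 0.806, and DESeq2 called 0. The miR-17/92 call ended without flaxseed 2 (median -0.24) or SDG 2 (-0.21), and with the level of miR-150 and miR-142-3p as a covariate (-0.17, adjusted p = 0.206). Without flaxseed 3, miR-1224 turned from 1.54 to -0.28 and miR-2141 from 2.01 to -0.36, and miR-27b was 0.33.

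Oil against SDG compares both components. The Dlk1-Dio3 list was lower in oil, with 20 of 22 members below 0 and a median of -0.43, which was 0.30 under positive control scaling, where all miRNAs had a median of 0.80 and the list stood at -0.50 against them. Leading members were miR-411 at -0.84 ± 0.27 (SE; n = 5 and 6), miR-381 at -0.76 ± 0.25 and miR-382 at -0.83 ± 0.33. The smallest p belonged to miR-499, encoded in a myosin gene, at 0.74 ± 0.23, higher in each of 5 oil lanes than in any SDG lane. Lower in each was miR-142-5p, at -0.91 ± 0.32. The lymphocyte and myeloid list had a median of 0.09 (adjusted p = 0.967).

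Camera's adjusted p for Dlk1-Dio3 was 8.35e-08, and 0.262 with an estimated correlation. Adjusted over the list alone, 0 of its members passed and miR-499 of the muscle list rose, against 0 over all 254. In edgeR 19 miRNAs (5 higher, 14 lower) had an unadjusted p under 0.05 with a smallest adjusted p of 0.45, and DESeq2 called 0. Positive control scaling called 17, all higher in oil.

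The remaining 16 lists were not called in any of the 6 comparisons in the fit as reported, and calls of some under alternatives are given below. Medians of the 8 luminal and epithelial miRNAs in flaxseed, oil and SDG against basal were -0.02, 0.19 and 0.22 (smallest adjusted p over the 6 comparisons 0.0892), and those of the 3 basal and keratinocyte miRNAs 0.09, 0.20 and -0.04 (0.387). In the same order of diets, the 20 adipocyte miRNAs had medians of 0.05, 0.06 and 0.07 (0.594) and the 10 endothelial miRNAs 0.16, 0.05 and -0.11 (0.183). The 9 fibroblast and smooth muscle miRNAs had medians of 0.08, -0.15 and 0.02 (0.608). Erythrocyte miRNAs had medians of 0.02, 0.38 and 0.10 (0.29), with miR-92a passing adjusted over the list alone in oil against basal and flaxseed against oil. Neuronal miRNAs had medians of 0.20, -0.31 and -0.11 (0.29), and liver and pancreas miRNAs 0.50, 0.49 and 0.18 (0.26). Among the families, let-7 had medians of 0.14, 0.07 and -0.07 (0.0892), miR-29 0.25, 0.25 and 0.34 (0.14), and miR-30 0.30, 0.11 and 0.12 (0.26). The miR-34 and p53 associated miRNAs had medians of -0.09, 0.39 and 0.02 (0.144), and the Sfmbt2 intron cluster 0.06, 0.41 and 0.30 (0.0892). Estrogen receptor associated miRNAs had medians of 0.01, 0.24 and 0.17 (0.106), breast oncogenic miRNAs 0.08, 0.11 and -0.12 (0.571), and tumour suppressor miRNAs -0.19, 0.06 and -0.03 (0.151).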

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

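Apart from the splits for miRNA lists, the tests here were chosen after the result was seen, the lymphocyte covariate and the fits without 3 lanes included; for the covariate, bounds on the medians and quartiles were written before its values were seen, 4 of 5 tests met those set against lymphocyte tissue, and the criterion on spread was set after these values were seen and revised once. At first it asked for fry past 0.05 or the quartile nearest 0 beyond 0.5 of the unadjusted median, which left 2 of the 5 against lymphocyte tissue, and now it asks for that quartile alone, which leaves 0 of 5 and also moved 2 of 3 tests of background counts to undecided. The need for each housekeeping mRNA to be low was likewise added after the counts were seen, which moved flaxseed 3 and SDG 5 to undecided.

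The Dlk1-Dio3 list was lower in oil than in basal and SDG lanes and higher in flaxseed than in oil lanes, with medians of -0.42, -0.43 and 0.63. The 3 lanes led by miR-720 as the whole cause are argued against, since without them the medians were -0.436, -0.296 and 0.551, with the members' quartiles nearest 0, at -0.268, -0.249 and 0.315, beyond 0.5 of the medians of all lanes (-0.21, -0.214 and 0.313), the last by little. After subtraction of each lane's negative control mean the medians were -0.392, -0.455 and 0.612, which argues against background counts as the whole cause in oil against basal (quartile -0.299), whereas quartiles of -0.177 and 0.304 fell short of the bounds in the other 2 comparisons and leave it open there. With the level of miR-150 and miR-142-3p as a covariate the medians were -0.273, -0.364 and 0.374 with quartiles of -0.202, -0.151 and 0.226, short of each bound, so that lymphocyte-rich tissue stays open in all 3 comparisons; camera at its preset correlation still called each and fry passed an unadjusted 0.05 in the latter 2, while an estimated correlation called none (adjusted p = 0.284, 0.446 and 0.54). An effect of the oil diet may contribute and was not tested apart from these comparisons, and cartridge and run are unknown.

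Lymphocyte miRNAs were high in 5 lanes, oil 1, oil 3, oil 4, SDG 1 and SDG 2, where miR-150 lay at 14.03 to 15.26 log2 CPM against 11.11 to 12.25 in the 11 basal and flaxseed lanes. Of the 11 oil and SDG lanes 4 lay within that range, and an effect of run or cartridge on the 5 lanes was not tested, as the files give neither. Lymphocyte-rich tissue, such as a lymph node left in the sample, stays open. Of 13 further list members 2 (miR-142-3p and miR-342-3p) had these 5 lanes as their highest, of 26334 possible sets. Of all 253 other miRNAs 9 did. The 9 include these 2, miR-19a, miR-19b, miR-92a and miR-106b of the miR-17/92 list, and miR-15b, miR-16 and miR-467f. With the covariate the miR-17/92 median of SDG against basal went from 0.35 to 0.154, as carried-over lymphocytes could give, while that of oil against basal went from 0.48 to 0.286 (quartile 0.193, bound 0.241), not past 0.05 with fry, and stays undecided; the calls of flaxseed against oil and against SDG ended too, at -0.33 and -0.17. The covariate was not fitted without the lanes led by miR-720. In flaxseed 3 miR-142-3p lay above the other flaxseed lanes, at 14.75 log2 CPM, while miR-342-3p lay below them, at 7.84. In basal 1 miR-142-3p was low, at 10.4, so the covariate may misstate lymphocyte levels in these lanes. Diet stays open too, with an exact permutation p of 0.0952 for miR-150 in oil against basal, adjusted p = 0.286 over the 3 diets.

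The miR-720 share was far above the other lanes of its group in basal 1, flaxseed 3 and SDG 5 (65.4%, 53.7% and 47.4%; gap over range 0.914, 0.96 and 0.925). A loss of all 4 housekeeping mRNAs is argued against in basal 1, whose summed count of 16038 lay within the 13365 to 26571 of its group. B2m alone was below its group there (4248 against 4752 to 11151). The bound against loss used the sum alone, so a partial loss of long RNA is not excluded in basal 1. Loss of long RNA stays open for flaxseed 3 (4767 against 9539 to 26370) and SDG 5 (8696 against 9966 to 25019), since the 4 mRNAs moved apart. In flaxseed 3 Actb (1123 against 3050 to 10665), B2m and Gapdh (9 each) were below and Rpl19 (3626 against 1122 to 3302) above the other lanes. In SDG 5 B2m (878 against 4209 to 8798) and Gapdh (129 against 214 to 460) were below, with Actb (5638) and Rpl19 (2051) within the group. A change of this probe alone is argued against in basal 1 and flaxseed 3. Without miR-720 their rank correlation with the median lane was 0.858 and 0.711, so that 2 of the 3 lanes lay below the 0.939 to 0.988 of the other 19 lanes. SDG 5 lay within that range at 0.957, so a change of this probe alone stays open there. The 3 lanes belong to 3 diets, and no biological explanation was tested.

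Further lanes stood apart from their group by the gap to the nearest lane over the group's range. In SDG 5 the total count was 686270 against 260550 to 393090 (0.689) and the share of probes above threshold 47.9% against 32.7% to 37.1% (0.714). The negative control mean of oil 1 was 19.75 against 18.125 to 18.375 (0.846), and the positive control mean of basal 4 was 1298.5 against 1087 to 1122 (0.835). miR-150 in flaxseed 3 stood apart at 0.762. miR-142-3p did in basal 1, at 10.4 log2 CPM against 12.3 to 12.5 (0.937), and in flaxseed 3, at 14.75 against 12.1 to 12.5 (0.847). miR-342-3p in flaxseed 3 was 7.84 against 10.0 to 10.4 (0.851). miR-410 stood above its group in all 3 lanes led by miR-720, at 0.718 in basal 1, 0.814 in flaxseed 3 and 0.725 in SDG 5. Of 64 checks 14 met the criterion, which chance meets in about 1 of 20 groups. Of 81 comparisons of control probes with basal lanes 0 passed (smallest adjusted p = 0.0877, exact permutation). That value belonged to positive controls A and D, each higher in every SDG lane than in every basal lane. Their means were 37440 against 29580 and 655.3 against 525.8 counts (exact permutation p = 0.002165 each). Lanes separated completely give the smallest p this test can reach, and it did not pass here. A technical difference between SDG and basal lanes is therefore not excluded. Controls A and D were also higher on average in oil lanes, at 34620 and 629.8 counts, without full separation from basal lanes (exact permutation p = 0.03175 each, adjusted p = 0.4286). For oil against basal lanes a technical difference is not excluded either.

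Real counts of miRNAs were 0 in each comparison, which 100 of 100 splits of the same lanes reach by construction, so that these splits say nothing about chance. The highest other counts were 12 for flaxseed, 8 for oil and 4 for SDG against basal, 5 for flaxseed against oil, 7 for flaxseed against SDG, 26 for oil against SDG and 14 for any diet. The same holds for the 0 lists of flaxseed against basal (100 of 100, highest other 4). Chance could not be excluded for the other list counts: of 100 splits, 51 called as many as the 3 of oil against basal (9) and 31 as the 3 of SDG against basal (6). For the other comparisons 49 called as many as the 2 of flaxseed against oil (6), 40 as the 2 of flaxseed against SDG (5) and 85 as the 1 of oil against SDG (11). Without the 3 lanes led by miR-720, the 31 miRNAs of flaxseed against oil were reached by 1 of 100 splits, the real one, with 28 as the highest other, and the 18 on the 254 probes kept by 2 of 100, with 30 as the highest other. Such counts were rare among the splits, but chance is not excluded, since other splits reached 28 and 30. The lanes were also left out after the data were seen, and all lanes gave 0. For flaxseed against oil 5 of 17 alternatives and 4 of 11 omissions of a lane gave any call. Splits that call 26, 14, 28 or 30 point to a structure of the samples, and which lanes they grouped was not examined.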

How the results depend on the processing

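The fits without the 3 lanes led by miR-720, with mouse probes only, total count without miR-720, housekeeping scaling without flaxseed 3 and the lymphocyte covariate, and the last fit and the first repeated with an estimated correlation, were chosen after the results were seen. Causes were not tested except where stated.

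The count of 0 miRNAs held in all alternatives for SDG against basal (17) and flaxseed against SDG (17), and in every omission of a lane except in flaxseed against oil. For flaxseed against basal 1 of 18 alternatives made calls, housekeeping scaling with 67. It shifts all miRNAs, with a low housekeeping count in flaxseed 3, and called 0 without that lane. For oil against basal 4 of 17 did, DESeq2 with 6, no filter with 1 (miR-1952) and both fits without the 3 lanes with 1 each (miR-338-3p). For flaxseed against oil 5 of 17 did, DESeq2 with 30, positive control scaling with 5, the stricter filter, which tests fewer probes, with 6, and the fits without the 3 lanes with 31 and, with the 254 probes kept, 18; omitting a lane gave 0 to 7. For oil against SDG positive control scaling gave 17 and the fit without the 3 lanes on the 254 probes 1 (miR-872). For any diet both fits without the 3 lanes gave 1 (miR-338-3p). The replicate block and the authors' log2 table called 0 in each comparison tested.

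Lists called went to 0 in oil against basal, SDG against basal, flaxseed against oil, flaxseed against SDG and oil against SDG with an estimated correlation, and with fry to 0, 0, 1, 0 and 0. An estimated correlation also gave 0 in these 5 with the lymphocyte covariate and without the 3 lanes, and 1 in flaxseed against basal without the 3 lanes (liver and pancreas). The lymphocyte covariate gave 9 lists in oil against basal and 1 in SDG against basal, where the lymphocyte list, which holds both covariate miRNAs, turned to -0.028. Without the 3 lanes 1 list was called in flaxseed against basal (liver and pancreas) and 5 in flaxseed against SDG, where housekeeping scaling left 1. Omitting a lane gave 0 to 1 lists in flaxseed against basal, 2 to 5 in oil against basal, 2 to 4 in SDG against basal, 2 to 4 in flaxseed against oil, 1 to 5 in flaxseed against SDG and 1 to 2 in oil against SDG. At these extremes stood basal 1 (tumour suppressor list) and flaxseed 3 (liver and pancreas), then oil 3, basal 4, flaxseed 5 and flaxseed 3; the miR-17/92 list was gained in oil against SDG without oil 6 or SDG 2. The luminal and epithelial list was called lower in flaxseed against SDG without flaxseed 3, flaxseed 5 or SDG 4 (medians -0.34, -0.50 and -0.32). It was also called lower in flaxseed against oil without flaxseed 5 or oil 3 (-0.52 and -0.45). In oil against basal it was called higher without oil 3 (0.35).

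Of the values of 92 named results under alternatives, 2462 kept direction and side of the threshold, 78 passed it and 32 reversed. In flaxseed against basal, housekeeping scaling turned miR-500 to 0.094, miR-297c to 1.12, mcmv-miR-M23-2 to 0.11, miR-125a-3p to 0.45, miR-297a+miR-466f+miR-669b to 1.31 and miR-155 to 1.12, and without flaxseed 3 miR-155 to 0.04 and miR-1224 to -0.001. Without the 3 lanes miR-3471 turned to 0.079, and, with the filter recomputed and the 254 probes kept, miR-1224 to -0.28 and -0.37, miR-30e to -0.12 and -0.20 and let-7i to -0.023 and -0.10; miR-29a turned to -0.008 in the latter. Over omissions of a lane miR-1224 ranged from -0.28, without flaxseed 3, to 1.78. In SDG against basal miR-3471 turned to 0.064 with limma-voom, 0.23 and 0.23 without the 3 lanes, and ranged from -1.68 to 0.47 over omissions of a lane, the latter without basal 1, and miR-20a+miR-20b to -0.25 under positive control scaling. In flaxseed against SDG miR-1224 turned to -0.35 and -0.43 without the 3 lanes and miR-2141 to -0.46 and -0.54; over omissions of a lane they ranged from -0.28 to 1.78 and -0.36 to 2.51, lowest without flaxseed 3. In oil against SDG positive control scaling turned miR-381 to 0.005, miR-99a to 0.18, miR-135a to 0.14 and miR-329 to 0.17.

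Against the fit as reported, housekeeping scaling moved the median of all miRNAs by 1.35, 0.33, 0.45, 1.07, 0.90 and -0.13 in flaxseed, oil and SDG against basal, flaxseed against oil, flaxseed against SDG and oil against SDG. Positive controls moved it by 0.31, -0.49, -0.35, 0.46 and 0.79 and total count by 0.31, 0.18, -0.24, -0.12 and 0.10 in these comparisons without the first. Other moves, and those with DESeq2 size factors or the 100 most abundant probes, were at most 0.1 in size. Low counts limit Dlk1-Dio3, with 3 of 22 members' mean counts below the mean threshold of 40.9. They also limit the liver and pancreas list, whose members' mean counts had a median of 47.1. Probe-specific background and cartridge were not run, as the files give neither.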

Other observations

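The comparison of table columns with lanes, the background shares, the fits without the 3 lanes and with the lymphocyte covariate, and their repeats with an estimated correlation, were chosen after the data were seen, while the Sfmbt2 list was fixed in advance.

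The positions of the SDG columns in the authors' log2 table did not match the lanes of the same number. Each of the 6 SDG columns correlated best with another SDG lane, the column of SDG 1 with lane SDG 2 at r = 0.99, against 0.911 to 0.976 with the lane of its own number. The 16 other columns correlated best with their own lane, and all 22 with a lane of their own diet, so that comparisons of diets do not rest on the order.

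The labels state that lanes with fewer than 75% of probes above background were excluded. In the 22 lanes 29.0% to 47.9% of probes lay above the mean plus 2 SD of the negative controls and 49.7% to 63.6% above their mean, and the labels do not state how the authors set their background.

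Replicate numbers gave no sign of pairing, although the SDG numbers are in doubt given the column order above, here and in the fit with replicate as a block. Over 31 pairs of lanes of different diets with the same number, the correlation of residual levels ranged from -0.62 to 0.53 with a median of 0.01 (0.02 over 150 other pairs) and 12 above 0.1, and 3 of 22 lanes correlated best with a lane of their number.

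The Sfmbt2 intron cluster lay below 0 for 8 of 8 members in flaxseed against oil (median -0.59) and in flaxseed against SDG (-0.42), and was not called in either (adjusted p = 0.126 and 0.0892). Without the 3 lanes led by miR-720 it was called in both, at -0.97 and -0.74, and in oil against basal at 0.68 (adjusted p = 0.00923, 0.000443 and 0.0406). With an estimated correlation it was called in none of these, with adjusted p of 0.724, 0.708 and 0.553. With the lymphocyte covariate it was called lower in oil against basal, at -0.34 (adjusted p = 0.0444, and 0.311 with an estimated correlation), and its median turned to 0.36 in flaxseed against oil and 0.058 in flaxseed against SDG, so its direction depends on the model.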
